A study of Homo sapiens with 2 samples.

How the data were processed

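Total RNA from PANC-1 cells was measured on 2 Agilent human miRNA arrays, 1 for cells given 100 µM chloroquine diphosphate for 12 h and 1 for control cells, so each group held 1 array and no replicate. Groups were taken from the sample labels. Per the file headers, the images were read with Agilent Feature Extraction 10.7.1.1 and its miRNA protocol on a 1-channel array design, and the labels give Cy3 as the dye. The labels' labelling protocol names a cRNA amplification kit, whereas the file headers name an miRNA protocol; which labelling was used was not settled from the sources used here. The 2 arrays lay on 2 slides, so slide, labelling and group cannot be told apart.

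The deposited scanner files hold spot intensity on a linear scale. Per the file headers, background had been subtracted and a spatial trend removed within each array, spots that stood apart from their replicates had been marked, and nothing had been scaled between arrays. Low values fall below 0 after the background subtraction. The authors' deposited value table holds log2 values, 1 per miRNA repeated at each of its spots, with medians of 2.54 for both arrays. Set against the scanner values, its slope per log2 unit of signal was 0.990 for the chloroquine array and 0.986 for the control array, above a log2 signal of 5. Its columns have nearly the same distribution and are not centred per miRNA, and the steps that made it are not given in the sources used here. It served as an alternative. The control file names genome build hg19 and gives probe sequences and, for 1702 of 5893 probes, a mapping to the genome. Coordinates are printed as that file gives them, and the reference table of another assembly was not used for positions. miRNA names are those of the array design.

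Each array held 53144 spots, of which 50980 carried probes for 2549 miRNAs, with 1000 negative control spots. Control spots and outlier-marked spots were left out, 1604 of the miRNA spots on the chloroquine array and 1686 on the control array being marked. No miRNA spot was saturated (0 on each array). The processed signals of the spots of a probe were averaged on the linear scale. A probe counted as detected where over 50% of its used spots were well above background, and a miRNA where any of its probes was. Probe means were divided by the array's 75th percentile over the 880 probes detected on both arrays (135.0 for chloroquine and 150.8 for control), summed per miRNA and taken to log2. A scaled signal of 1 is therefore the level of that percentile. Differences are chloroquine minus control for miRNAs detected on both arrays. Their standard errors come from the spread between spots within each array and leave out cultures, RNA preparations, labelling and slides. With 1 array per group no test was run and no p-value is given, and the number of arrays limits the precision.

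Before the data were examined, 18 miRNA lists and the rule for named miRNAs were fixed. The rule takes the 10 brightest miRNAs on the control array, then the 12 largest positive and the 12 largest negative differences. These came from miRNAs detected on both arrays with a mean signal at or above the median, a difference over 2 standard errors and all their detected probes moving the same way, which 180 miRNAs met. It also takes the 5 brightest miRNAs detected on each array alone, and up to 4 members of each list with the largest absolute differences. A list with at least 3 members detected on both arrays was described by its median and by the percentile of that median among 10000 random lists of the same size, matched on 10 classes of mean signal. A list counted as standing apart outside the central 95%. This percentile describes these 2 arrays and is not a test across cultures. A miRNA detected on 1 array has only a bound on the other, given as at least N-fold over the higher of the lowest signal well above background there and the miRNA's own signal.

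The steps were tested on simulated arrays for the comparison of chloroquine with control, built from the control array's probe means with a scale ratio of 0.8 and a list of miRNAs shifted by 0.3. With 200 further miRNAs changed by known amounts, many of the lowered ones being lost from detection, the ratio found was 0.893 and the differences of the 429 miRNAs detected on both simulated arrays lay a median of -0.16 from the truth. At a true log2 difference of 1.5 the median found was 1.33 (48 miRNAs), and at -1.5 it was -1.66 (25 miRNAs). The scaling therefore moves 0 where many miRNAs change by large amounts. After that result the simulation was repeated with 60 changed, and the ratio found was 0.796 over 440 miRNAs, with a median error of 0.0081. There the medians found were 1.53 at 1.5 (15 miRNAs) and -1.50 at -1.5 (9 miRNAs). Once the median error was taken off, 96.5% of the 429 and 93.9% of the 440 lay within 2 standard errors of the truth. Beyond the set changes and scale, the simulated arrays differed only by noise between spots. They held no slide, labelling or culture difference, so these shares bear on spot noise alone. In each of these simulations 4% of 100 random lists of unchanged miRNAs lay outside the central 95%, and the shifted list lay above it. In a simulation with a line in probe GC content of 0.06 per 10 percentage points and 60 changed, over 449 miRNAs, the slope found was 0.062. There the ratio found was 0.856 and the median error -0.099, so the scaling also moved 0 under a trend in probe GC. GC content was taken from the longest probe of each miRNA.

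The alternatives were scaling by the 75th percentile over all probes, by the median or not at all, quantile normalization, limma's normexp background correction with an offset of 50, the mean of probe differences or the brightest probe per miRNA, the deposited total gene signal, the deposited detection call per miRNA, only miRNAs at or above the median signal, no detection filter, outlier-marked spots kept, odd or even spots alone, and the authors' value table. Scaling by spike-in control probes and the sum of the deposited total probe signals were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for the normexp correction.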

Results

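The miRNAs of PANC-1, an established line from a human pancreatic ductal carcinoma, were profiled in cells given 100 µM chloroquine diphosphate for 12 h and in control cells. Chloroquine is a weak base that collects in lysosomes and blocks the last step of autophagy, the breakdown of cell contents in lysosomes, and the labels call the treated cells autophagy-inhibited. Each condition was measured once, on 1 array. Of 50980 miRNA spots, 9428 (18.5%) were well above background on the chloroquine array and 9055 (17.8%) on the control array. These spots gave 527 detected miRNAs with chloroquine and 507 without, out of 2549 on the array. The median coefficient of variation between spots of a detected probe was 8.26% on the chloroquine array and 8.84% on the control array. No difference has a replicate check, and the errors given are standard errors from spots within the arrays.

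The comparison of chloroquine with control asks which miRNAs differ when autophagy is blocked in these cells. On the chloroquine array, miR-4485-3p, which matches mitochondrial ribosomal RNA sequence, was 1.81-fold higher (log2 difference 0.86 ± 0.03 SE), and miR-1973 was 1.80-fold higher (0.85 ± 0.01). GC-rich and RNA-fragment-like miRNAs were higher as a list, with a median difference of 0.31 over 33 members that stayed above 0 under every scaling tried but was -0.0012 once a line in probe GC and signal was taken out. Members of the imprinted cluster at 14q32 were lower as a list, with a median of -0.09 over 27 members that stayed below 0 under every scaling tried, and miR-377-3p of that cluster differed by -0.67 ± 0.03. The oncogenic miR-21-5p, among the 10 brightest on the control array, was at about the same level on both arrays, at scaled signals of 361 and 372 (-0.04 ± 0.02).

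Among the miRNAs taken for the largest positive differences, miR-4485-5p, from the same hairpin as miR-4485-3p, reached a scaled signal of 19.3 with chloroquine against 11.5 without (0.74 ± 0.02). The probe of miR-4485-3p, TTAGGGTACCGCGGC, is mapped in the control file to chromosome 11, 10529853 to 10529866 (hg19). The signal of miR-1273g-3p was 89.7 against 51.8 (0.79 ± 0.01), and that of miR-1246, a fragment of U2 small nuclear RNA, 14.3 against 9.34 (0.61 ± 0.03). miR-5684 differed by 0.82 ± 0.09 and miR-4430 by 0.64 ± 0.03. The other members of this group were miR-1587, miR-5787, miR-6125, miR-6869-5p and miR-2861, between 0.54 and 0.62.

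The largest negative difference among these brighter miRNAs was that of miR-6826-5p, at a signal of 1.78 with chloroquine and 3.18 without (-0.84 ± 0.02). Next came miR-377-3p, whose probe lies on chromosome 14 from 101528434 to 101528452 (hg19), and miR-6085 (-0.63 ± 0.02). The 3p arms of oncogenic hairpins were in this group. miR-31-3p differed by -0.57 ± 0.04 from a control signal of 3.71, and the signal of miR-21-3p was 0.927 against 1.31 (-0.50 ± 0.03), while miR-31-5p differed by 0.08 ± 0.02. The hypoxia-induced miR-210-3p, with its probe on chromosome 11 from 568161 to 568175 (hg19), was 1.31-fold lower (-0.39 ± 0.04). The signal of miR-4284 was 21.0 against 31.6 (-0.59 ± 0.01). The remaining members were miR-7114-5p, miR-6165, miR-1275, miR-19a-3p and miR-3659, between -0.60 and -0.51.

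**Figure D1:**
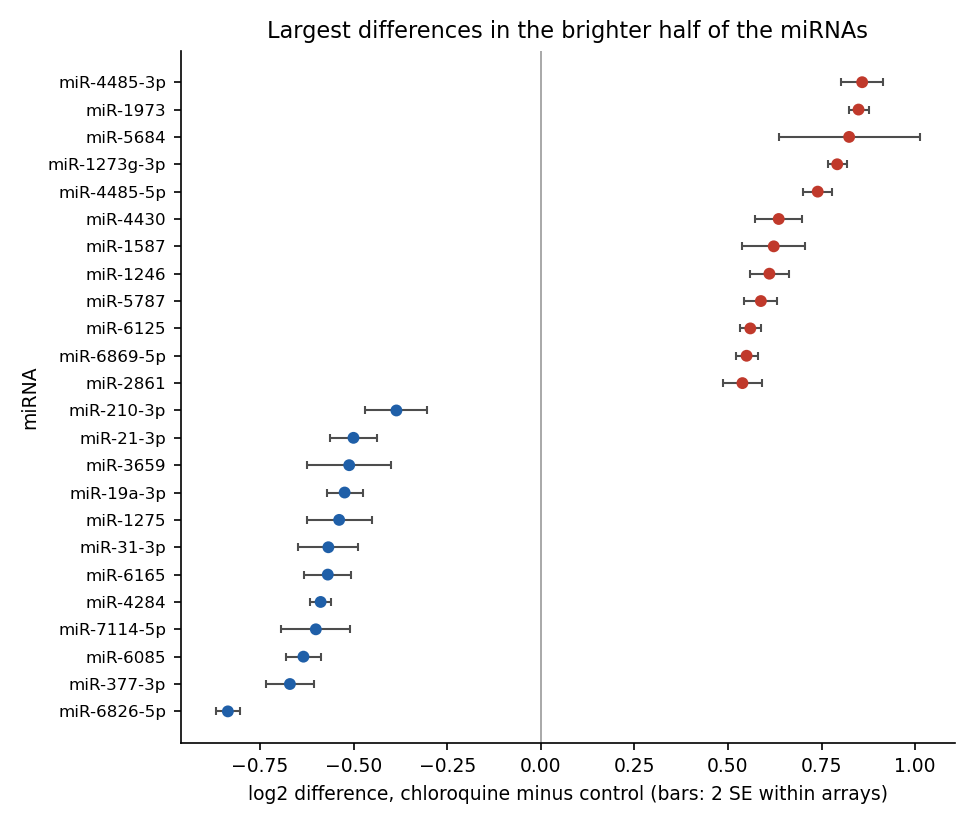
The log2 difference, chloroquine minus control (horizontal axis), of the 12 largest positive and 12 largest negative differences among miRNAs at or above the median signal; points are single values from 1 array per group and bars are 2 standard errors within arrays. The values run from 0.86 for miR-4485-3p to -0.84 for miR-6826-5p.

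The brightest miRNAs on the control array differed little or in both directions. miR-7975 and miR-7977 held 54.5% of the detected signal on the chloroquine array and 58.5% on the control array. miR-7975 differed by -0.20 ± 0.01 and miR-7977 by -0.01 ± 0.01. miR-7641 was 1.43-fold higher (0.51 ± 0.02) and miR-5100 was 1.28-fold lower (-0.35 ± 0.01). The tumour-suppressive let-7a-5p had signals of 77.2 and 68.7, and miR-29a-3p had 65.5 and 66.1. miR-494-3p, miR-8069 and miR-23a-3p differed by 0.14, 0.05 and 0.06, and the sign of each turned without scaling, where they differed by -0.02, -0.11 and -0.10.

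Only 3 miRNAs were at least 2-fold higher and 3 at least 2-fold lower, and all were dim, with scaled signals of at most 0.574. They are named here after their values were seen. The higher ones were miR-7515 (1.13 ± 0.08), miR-664b-5p (1.06 ± 0.07) and miR-424-3p (1.01 ± 0.08). The lower ones were miR-154-3p, whose hairpin lies in the 14q32 cluster (-1.44 ± 0.08), miR-7-5p, a miRNA of neuroendocrine cells (-1.10 ± 0.10), and miR-663a (-1.08 ± 0.08). Each except miR-154-3p had 1 of its 2 probes detected on both arrays. None of the 6 was 2-fold with the normexp background correction. At a 1.5-fold limit the counts were 28 higher and 13 lower. By over 2 standard errors, 211 of the 484 miRNAs detected on both arrays were higher and 124 lower, with 149 within.

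**Figure D2:**
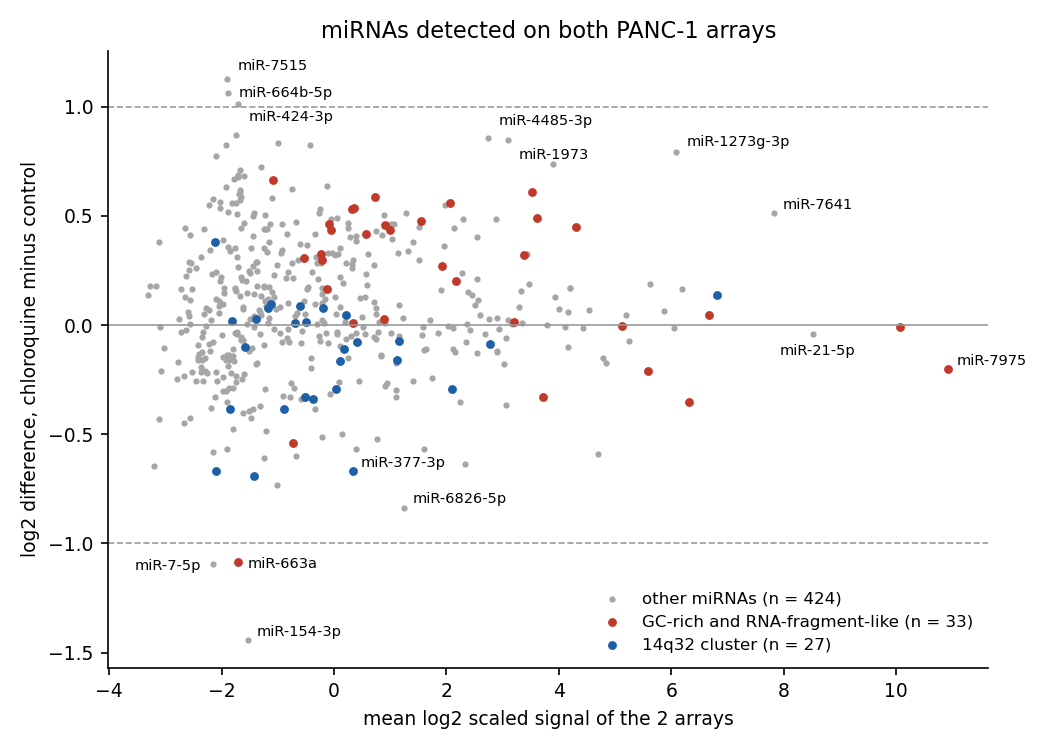
The log2 difference, chloroquine minus control (vertical axis), against the mean log2 scaled signal of the 2 arrays for the 484 miRNAs detected on both; each point is 1 miRNA, red points are the 33 GC-rich and RNA-fragment-like miRNAs, blue points the 27 of the 14q32 cluster, and dashed lines mark a 2-fold difference. The 6 miRNAs past 2-fold, such as miR-7515 at 1.13 and miR-154-3p at -1.44, lie at low signal.

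GC-rich and RNA-fragment-like miRNAs, many of which overlap ribosomal or other structural RNAs, stood apart at the 99.99th percentile of random lists matched on signal alone, and no longer did so once a line in probe GC and signal, fitted on the other miRNAs, was taken out (median -0.0012, percentile 59.3). Of the 33 members, 22 were higher and 6 lower by over 2 standard errors, and 21 lay above the median of all miRNAs. miR-3656 differed by 0.66 ± 0.04, miR-1246 by 0.61 ± 0.03 and miR-5787 by 0.59 ± 0.02, while miR-663a went the other way (-1.08 ± 0.08). The median probe GC content of this list was 83.3%, and differences on these arrays followed probe GC in general. The median difference was 0.00027 in the 161 miRNAs of lowest GC, 0.06 in the middle 161 and 0.21 in the 162 of highest GC, with a Spearman correlation of 0.27 across miRNAs, which are not independent replicates.

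**Figure D3:**
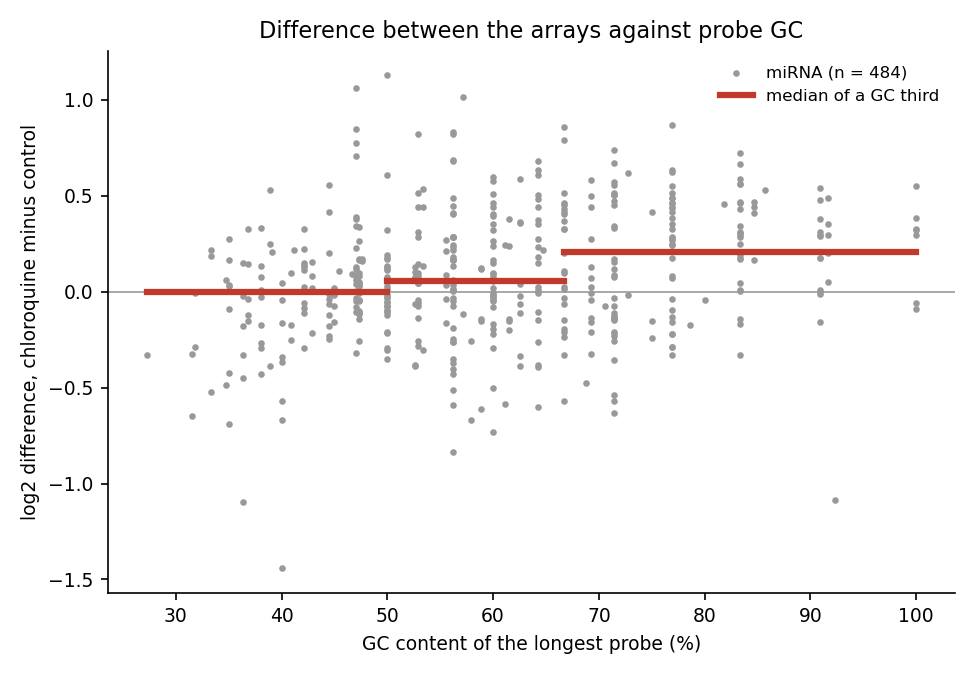
The log2 difference, chloroquine minus control (vertical axis), against the GC content in percent of each miRNA's longest probe; each point is 1 of 484 miRNAs and red lines are the medians of 3 groups of rising GC. The medians are 0.00027, 0.06 and 0.21.

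The 14q32 cluster, a large imprinted group of miRNAs, lay at the 0.225th percentile of random lists. Of its 27 members detected on both arrays, 15 were lower, 2 higher and 10 within 2 standard errors, and 6 lay above the median of all miRNAs. The dim miR-376b-3p differed by -0.69 ± 0.05, with its probe on chromosome 14 from 101506837 to 101506855 (hg19). The dim miR-758-3p differed by -0.67 ± 0.17 and the dim miR-543 by -0.39 ± 0.07. Of their probes, 1 of 4 and 1 of 2 were detected on both arrays, and 1 of 2 for miR-376b-3p. The 2 members higher by over 2 standard errors were miR-494-3p, which was lower without scaling, and miR-134-5p (0.38 ± 0.08), the latter named after its value was seen. This list and the GC-rich list were the 2 of 16 with at least 3 members that lay outside the central 95%. With randomly drawn members, 0.8 would lie outside by chance. Once the line in probe GC and signal was taken out, the GC-rich list lay inside (percentile 59.3) and the 14q32 list still outside (1.16). The 2 lists are therefore not read as an excess over 0.8. Whether members of a cluster or family behave as randomly drawn ones was not tested.

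With the main settings the other families lay within the central 95% of random lists. All 4 members of the miR-181 family were higher by over 2 standard errors, with a median of 0.33 at the 96.9th percentile that stayed above 0 under every scaling tried. This list lay outside the central 95% with quantile normalization (percentile 98.2), the mean of probe differences (98.7) and the brightest probe (98.2), and at -1.34 with the deposited total gene signal. miR-181a-5p differed by 0.40 ± 0.03 and the dim miR-181d-5p by 0.44 ± 0.08. Both miR-181d-5p and miR-181c-5p had 1 of 2 probes detected on both arrays, at control signals of 0.172 and 0.166. Of 9 let-7 family members, 7 were higher and 2 within 2 standard errors, with a median of 0.16 at the 86.5th percentile. That median was -0.0020 without scaling, although 7 of 9 members lay above the median of all miRNAs. In the oncogenic miR-17-92 cluster and its paralogs the median was -0.07 over 12 members, 7 of them lower and 1 higher, and it was negative under every scaling tried and outside the central 95% with the brightest probe (percentile 1.45). miR-19a-3p (-0.52 ± 0.02) and miR-19b-3p (-0.36 ± 0.03) stood at the low end, and miR-92a-3p (0.36 ± 0.02) at the high end. The miR-23/27/24 clusters had a median of -0.07 over 5 members, which was 0.0035 in the authors' value table. Medians of the miR-30, miR-29 and miR-15/16 families were 0.06, -0.02 and 0.0035, and none kept its sign under every scaling, with -0.098 and -0.16 for the miR-30 and miR-15/16 families without scaling and 0.0011 for miR-29 with spike-in scaling. Among their members detected on both arrays, miR-30d-5p (0.28 ± 0.02) and miR-424-5p (-0.18 ± 0.02) differed most.

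Lists chosen for autophagy and lysosomes did not stand apart. Of 33 miRNAs on the array that are known to target autophagy genes, 23 were detected on both arrays, with 7 higher, 8 lower and 8 within 2 standard errors and a median of 0.0042 (27.5th percentile), which was -0.16 without scaling. Its widest differences were those of miR-630 (0.82 ± 0.05), miR-376b-3p, miR-101-3p (-0.43 ± 0.07) and miR-181a-5p. All but miR-181a-5p were dim, each with 1 of 2 probes detected on both arrays. In the TFEB and lysosomal list, named for the regulator of lysosome genes, the median over 5 members was -0.05 and negative under every scaling tried, with 2 lower, 0 higher and 3 within 2 standard errors. miR-29b-3p differed by -0.17 ± 0.02 and miR-30b-5p by -0.12 ± 0.05.

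Pancreatic cancer oncogenic miRNAs had a median of 0.05 over 22 members, 10 higher and 6 lower, which was -0.11 without scaling. miR-132-3p (0.45 ± 0.04) and miR-212-3p (-0.48 ± 0.08), neighbours on chromosome 17 with probes starting at 1953267 and 1953641 (hg19), differed in opposite directions. All 8 detected p53-induced miRNAs lay within 2 standard errors of 0, with a median of 0.03 (-0.13 without scaling), miR-34a-5p at -0.06 ± 0.03 among them. In the stress-response list 5 of 12 were higher and 5 lower, with a median of -0.0076 that was 0.013 with spike-in scaling, miR-638 at 0.53 ± 0.03 and miR-630 high, and miR-663a low. Mirtrons, with a median probe GC of 73.9%, had a median of -0.01 over 6 members, 0.0083 with spike-in scaling, from miR-1224-5p at 0.62 ± 0.05 to miR-1238-3p at -0.32 ± 0.06. Of 25 markers of other cell types on the array, 4 were detected on both arrays, and 21 on neither, with a median of 0.01 that was -0.15 without scaling. Beside miR-7-5p these were miR-9-5p (0.14 ± 0.04, and -0.02 without scaling), miR-486-5p (0.09 ± 0.10) and the endothelial miR-126-3p (-0.07 ± 0.03). In the primate cluster at 19q13, 19 of 20 were detected on neither array, and miR-516a-5p differed by 0.16 ± 0.10. In the list of the epithelial miR-200 family, which also held miR-205-5p, no member was detected on both arrays (0 of 6). Its member miR-200c-3p, named after its value was seen, was detected with chloroquine at a signal of 0.127. It was not well above background on the control array.

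**Figure D4:**
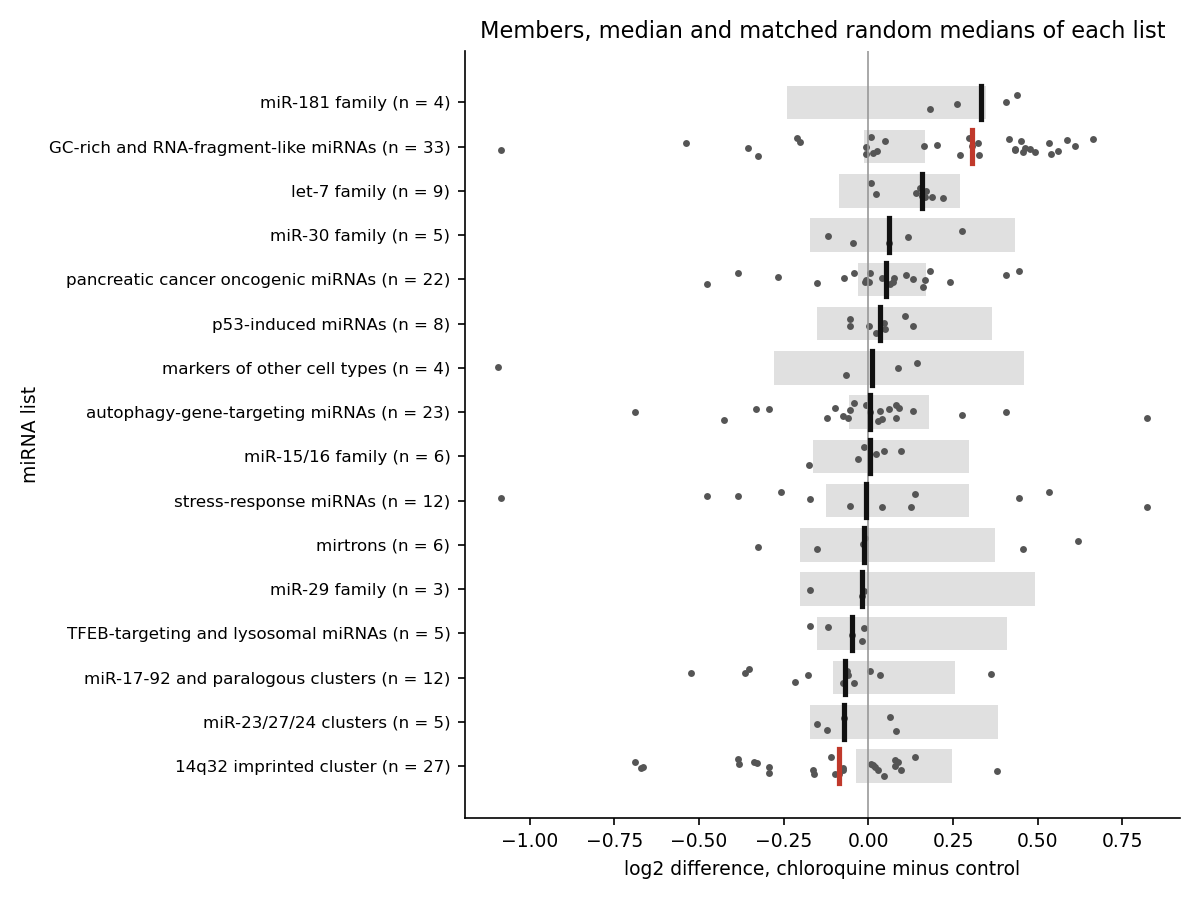
The log2 difference, chloroquine minus control (horizontal axis), of the members of each of 16 miRNA lists detected on both arrays; dots are members, thick lines medians and grey bars the central 95% of medians of 10000 random lists matched on signal. The medians of the GC-rich list (0.31) and the 14q32 list (-0.09), in red, lie outside their bars; the first was -0.0012 and no longer apart once a line in probe GC and signal was taken out.

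Detection differed for few miRNAs. With chloroquine alone 43 were detected, and in control alone 23, all dim. The brightest of the first were miR-501-3p (at least 1.26-fold), miR-3654 (at least 1.64-fold) and miR-622 (at least 1.49-fold), with miR-662 and miR-550a-5p, whose signals on the 2 arrays lay within 2 standard errors of each other. The brightest of the second were miR-503-5p of the miR-15/16 family (at least 2.55-fold), let-7b-3p (at least 1.31-fold), miR-138-2-3p (at least 1.63-fold), miR-6851-3p (at least 1.26-fold) and miR-3675-3p (at least 1.36-fold). Each of these bounds equals the ratio of the measured signals, which carries the error of dim spots.

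Across the 484 miRNAs the log2 signals of the arrays correlated at a Pearson r of 0.989, and the differences had a median of 0.06 and a standard deviation of 0.33, against a median standard error of 0.047 from spots. The scaling set where 0 lay: without it the median of all miRNAs moved by -0.16, and with the percentile over all probes by -0.11, while the counts of members above the median of all miRNAs do not move with a single factor per array. With the main scaling 59.3% of miRNAs were higher, against 38.6% without scaling, 44.2% with the percentile over all probes, 47.1% with quantile normalization and 71.5% with normexp. The counts of 28 higher and 13 lower at 1.5-fold became 11 and 26 without scaling, 14 and 22 with the percentile over all probes, 14 and 23 with quantile normalization, 20 and 18 with median scaling and 16 and 12 in the authors' value table. The counts of 211 and 124 past 2 standard errors became 138 and 232 without scaling, 153 and 209 with the percentile over all probes and 162 and 190 with quantile normalization. At 2-fold the 3 and 3 became 0 and 3 without scaling, and 1 and 3 with either of the other settings.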

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

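Control probes outside the miRNA comparison, divided by the same factors as the miRNAs, also differed between the arrays. The 4 hur_1 probes were all brighter with chloroquine, with a median log2 difference of 0.16, and the 4 hur_4 probes likewise, with a median of 0.23. What these probes target is not given in the sources used here. Other control probes differed in the opposite direction, by a median of -0.59 for 3 hur_6 probes, -0.15 for 4 mr_1 probes, -0.08 for 4 hur_2 probes and -0.80 for the bright corner spots, while 4 hur_5 probes differed by 0.07. The 8 spike-in probes well above background on both arrays ran from -0.11 to 0.07. With 1 array per group, each on its own slide, no biological explanation was tested for these values.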

How the results depend on the processing

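Scaling by the spike-ins and the sum of total probe signals were chosen after seeing the data. Over 17 alternatives, 264 of 269 list values kept their side of the central 95%. Settings with a single factor per array (the percentile over all probes, no scaling, median and spike-in scaling) cannot move a list's percentile. Their list values kept their side by construction, so only the other settings bear on it. The GC-rich list (median 0.15 to 0.33) and the 14q32 list (-0.25 to -0.03) kept direction and side in each alternative. None of the alternatives takes out the trend in probe GC that ended the call of the GC-rich list. Of 82 named miRNAs, 66 had no difference over 2 standard errors that changed sign. No paired analysis was possible because each group held 1 array. Dim miRNAs limit the comparison: at or above the median signal the standard deviation was 0.30, with 0 miRNAs past 2-fold in either direction, since all 6 were dimmer. Except where a reason is given, the cause of a change was not tested.

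With the 75th percentile over all probes the median was -0.045, 1 miRNA was 2-fold higher, and the signs turned of miR-8069 (-0.057), miR-23a-3p (-0.041), miR-195-5p (-0.0092), miR-30a-5p (-0.044) and miR-23b-3p (-0.024). Without scaling the median was -0.099, 0 miRNAs were 2-fold higher, and miR-494-3p (-0.024), miR-8069 (-0.11), miR-23a-3p (-0.095), miR-195-5p (-0.064), miR-30c-5p (-0.043), miR-30a-5p (-0.098), miR-23b-3p (-0.078) and miR-9-5p (-0.018) turned. Both settings, and median scaling (median 0.011, miR-8069 at -0.0019), moved all miRNAs by 1 amount. Spike-in scaling gave a median of 0.082. With quantile normalization the median was -0.027, 1 miRNA was 2-fold higher, the miR-181 list passed the central 95% at 0.29, and miR-494-3p (-0.028), miR-8069 (-0.18), let-7f-5p (-0.0080), let-7b-5p (-0.036), miR-195-5p (-0.0087), miR-30a-5p (-0.044), miR-23b-3p (-0.037) and miR-24-3p (0.014) turned. In the authors' value table the median was 0.010, the standard deviation 0.31, 0 miRNAs were 2-fold higher, and let-7b-5p (-0.026), miR-195-5p (-0.063), miR-24-3p (0.0035) and miR-9-5p (-0.013) turned.

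With normexp the standard deviation was 0.16 and 0 miRNAs were 2-fold higher and 0 lower, since its offset draws dim differences towards 0. The mean of probe differences (0.36) and the brightest probe (0.35) took the miR-181 list past the central 95%, and the brightest probe took the miR-17-92 list past it (-0.10). The deposited detection call gave 6 miRNAs 2-fold lower and a standard deviation of 0.35. Without a detection filter 146 were 2-fold higher and 96 lower, with a standard deviation of 1.09, over 1295 miRNAs, most of them not well above background on both arrays.

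The deposited total gene signal gave 16 miRNAs 2-fold lower, a median of 0.0080, a standard deviation of 0.62 and a miR-181 list at -1.34, and turned miR-1587 (-0.21), miR-17-3p (0.017), miR-181d-5p (-2.84), miR-181c-5p (-2.96) and miR-758-3p (0.86). These totals carry signal of other miRNAs, as the other observations show. The sum of the deposited total probe signals gave a median of 0.022 and moved no list across the central 95%, with no miRNA named here changing sign past 2 standard errors.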

Other observations

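The check of the deposited gene totals was chosen only after its result was seen; the other tests were set after the patterns were noticed and before their own results. In a pair of hairpins, picked after their values were seen, the arms differed unequally, unlike those of miR-4485, which were both higher. In the miR-21 hairpin the bright arm miR-21-5p differed by -0.04 ± 0.02 and miR-21-3p by -0.50 ± 0.03, and in the miR-31 hairpin miR-31-5p differed by 0.08 ± 0.02 and miR-31-3p by -0.57 ± 0.04. A hypothesis that dimmer arms were lower in general was tested on 45 other hairpins with both arms detected. The dimmer arm minus the brighter had a median of -0.036, at the 47.5th percentile of 2000 random draws of pairs matched on signal, with a standard deviation of 0.42 between hairpins, and was below 0 in 25 of 45, which argues against a general lowering of that size.

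The deposited total gene signals held carried-over values. Among miRNAs called detected in the files, 155 of 650 on the chloroquine array and 153 of 633 on the control array had a total gene signal that differed by over 5% from the sum of their deposited total probe signals. In all 121 cases above the sum on the chloroquine array, and all 125 on the control array, the total equalled that of the preceding detected miRNA in name order plus some of the miRNA's own probes, within 0.002 signal units plus 2e-05 of the total. With a randomly chosen miRNA in place of the preceding one, such matches averaged 0.35 and 0.15. On the control array miR-29a-5p was given 1887, its probes summed to 0.904 and the preceding miR-29a-3p had 1886. miR-765 was given 3521, after miR-7641 at 3519. All 34 and 28 cases below the sum equalled the total of some of the miRNA's own probes. Apart from the alternative built on them, no value reported here uses these totals.

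The higher signal of GC-rich and RNA-fragment-like miRNAs may follow from a trend in probe GC. After a line in probe GC and signal, fitted on the other miRNAs, was taken out, the list median went from 0.31 to -0.0012, at percentile 59.3 of random lists. Outside the list, 95 miRNAs of the same GC range had a median of 0.19. The spike-in probes, divided by the same factors as the miRNAs, had a median of -0.020. That scaling had already taken out any factor common to a whole array, so this value does not test for one. A slide or labelling difference that depends on sequence cannot be told apart from chloroquine. Neither can a change in the RNAs from which these fragments come.

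The lower signal of the 14q32 cluster was not removed by the same line, which argues against the GC trend as its whole cause. Its median was -0.12 afterwards, at percentile 1.16 and just outside the central 95% of random lists, which began at -0.11. The spike-in median of -0.020 again leaves open a slide or labelling difference that depends on sequence. A lower level of the cluster in chloroquine-treated cells remains a hypothesis, and it cannot be told apart from a difference between cultures.

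A candidate explanation for the higher miR-4485-3p, miR-4485-5p and miR-1973 is more RNA of mitochondrial sequence, as these miRNAs match the mitochondrial genome. The trend in probe GC did not account for them, since their median difference stayed at 0.73 after the line was taken out. The check was limited to 3 further miRNAs named beforehand as of mitochondrial sequence (miR-4461, miR-4463 and miR-4484), and others of such sequence were not sought. Of these 3, only miR-4484 was detected on both arrays, at 0.075 ± 0.06. The rule took the median over those of the 3 detected on both arrays, and this value lies under the limit of 0.2 set against the hypothesis. That median rests on 1 dim miRNA, which is too few to decide. A slide or labelling difference was not tested for these miRNAs, so the hypothesis stays open.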
